A study of Mus musculus with 18 samples.

How the data were processed

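Total RNA of cortex and striatum, dissected together from mice aged 6 weeks, was split by tail length in the study, per the labels' protocols: RNA bound to poly(U) agarose was released with 25% formamide (WASH, enriched for short poly(A) tails) and then with 90% formamide (ELUTED, enriched for long tails), beside unfractionated RNA (INPUT). Per the labels' protocols, 5 ng of RNA was amplified over 21 cycles and 8 µg of cDNA was fragmented, labelled with biotin and hybridised. The groups come from the labels: WT, CPEB4 GT/+ and CPEB4 KO, with 2 animals each and 3 fractions per animal, 18 arrays in all. The labels' series text calls the arrays PrimeView mouse arrays, while the probe set names in the deposited table carry the PM mark of another mouse design. The names in the table were used, through the probe set to gene table supplied with the data.

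The deposited table holds log2 values made by the authors with RMA, per the submitters' processing notes, which name no version and no annotation. The values ran from 3.45 to 13.66, and the array medians from 6.32 to 6.48. RMA normalizes the arrays to each other, so a difference in the total amount of poly(A) RNA between fractions or genotypes was not measured. The deposited values still differed in spread. The standard deviation across probe sets ran from 1.78 to 1.90 on ELUTED arrays and from 1.96 to 2.01 on WASH arrays. All differences below are relative to the other genes on the same arrays.

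Of 45141 probe sets, 104 controls were set aside, 28898 carried 1 gene symbol and were used, and 551 with several symbols and 15692 without a name here, controls included, were left out. By Entrez identifier, 28689 of them matched the RefSeq table, which served for names and for gene order only, and 0 symbols changed. Each gene was represented by its probe set with the highest mean over the 18 arrays, which gave 17097 genes. The lowest 25% by that mean were left out, which put the filter at 5.52, near the highest mean of 23 nonspecific control probe sets (5.61). The 12822 genes kept were tested in every comparison, and 6407 of them had more than 1 probe set. The number of arrays limits the precision: the fits had 3 residual degrees of freedom, and an exact test of 2 animals against 2 cannot go below p = 0.333.

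For each animal the log2 ELUTED value minus the log2 WASH value was taken per gene (the ELUTED over WASH ratio). Linear models with genotype means were fitted with limma 3.58.1 (lmFit, contrasts.fit and eBayes, without trend) in R 4.3.3, with all 6 animals sharing 1 estimate of the spread. There were 8 comparisons: the ratio against 0 over the 3 genotypes and in WT, and each of the 3 pairs of genotypes in INPUT and in the ratio. All tests were two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 12822 genes were called. Standard errors (SE) of contrasts are limma's moderated ones, and standard deviations (SD) are between animals.

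There were 24 gene lists: 10 of cell types or other tissue (cortical excitatory, striatal projection and GABA interneuron genes; astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial and mural, ependymal with choroid plexus and meningeal, and blood genes), genes of other brain regions, pre- and postsynaptic genes, autism risk genes, poly(A) tail machinery, unfolded protein response (UPR), cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation subunits, glycolysis, replication-dependent histones, immediate early genes, nuclear or untailed noncoding RNA, mitochondrially encoded genes and sex-linked genes. Lists with at least 5 kept members were tested against the other genes with camera at its preset correlation of 0.01, adjusted over the 22 lists tested in a comparison. The mitochondrially encoded and the sex-linked list had too few kept members. Camera with an estimated correlation, and fry, which asks whether a list's genes move on balance one way, were run beside it (fry and duplicateCorrelation use statmod 1.5.0). All 46 list calls at the preset correlation were lost with an estimated correlation, and 40 were lost with fry.

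Genes named in the text follow a rule: Cpeb4; per comparison up to 10 higher and 10 lower genes with the largest called differences and no overlap between the groups' animals (for a ratio against 0, all animals on 1 side); where fewer than 10 genes were called, up to 5 higher and 5 lower with the smallest unadjusted p among those without overlap and with a log2 difference of at least 0.58; and up to 2 members with the largest change, and up to 2 with the highest level, of each list past its test. Members with the highest level are named for ELUTED over WASH over the 3 genotypes, and no list members are named for WT alone. The comparisons, lists, naming rule and most alternatives were fixed before the data were examined. The pituitary hormone list was chosen after the data were seen.

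The fits were tested on simulated data of 12822 genes built with the spread of these data. The noise was drawn independently for each gene and animal, and 50 genes were changed at each size. In the real data genes move together within an animal and far more differ between fractions, so the shares below need not hold for them. For ELUTED over WASH over the 3 genotypes, 64% of changes of log2 0.6 and 86% of changes of log2 1 were recovered. For INPUT of CPEB4 KO against WT these shares were 42% and 84%. For the ELUTED over WASH ratio of CPEB4 KO against WT, 0% of changes of log2 0.6, 28% of log2 1 and 78% of log2 2 were recovered.

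Alternatives, whose effects the closing section gives, were: no filter or the lowest 50% of genes left out; the mean of a gene's probe sets; quantile normalization within each fraction; arrays centred on their medians; eBayes with trend and robust settings; all 18 arrays in 1 fit, with the animal as a random block or with none; the replicate number as a block across genotypes; fits of only the 2 genotypes compared; INPUT in place of WASH as the denominator; and each animal left out in turn. Added after seeing the data were ratios scaled to a common spread per animal, arrays aligned on the hybridisation controls, leaving out replicate 2 of both CPEB4 GT/+ and CPEB4 KO, a block that crosses the replicate numbers, and the mean of an animal's 3 fractions for the INPUT comparisons. The planned test of sequence elements in 3' UTRs was not run, since no genome sequence was used here.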

Results

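Cortex and striatum of 6 mice aged 6 weeks were profiled on 18 arrays: 2 WT animals, 2 CPEB4 GT/+ animals, heterozygous for the GT allele of Cpeb4, and 2 CPEB4 KO animals. CPEB4 is a cytoplasmic RNA-binding protein that acts on the poly(A) tails of mRNAs. Each animal gave an INPUT array of total RNA, a WASH array of RNA enriched for short poly(A) tails and an ELUTED array of RNA enriched for long tails. Arrays of the same group correlated at r = 0.966 to 0.994 across genes, which are not independent replicates, and WASH with ELUTED arrays at 0.877 to 0.976.

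The mean level of Cpeb4 itself stepped down with genotype in all 3 fractions. At its probe set with the highest mean, the INPUT level was 7.89 ± 0.37 (SD, n = 2) in WT, 7.16 ± 0.22 in CPEB4 GT/+ and 6.77 ± 0.21 in CPEB4 KO on the log2 scale. In WASH the means were 8.74, 8.30 and 7.59, and in ELUTED 7.76, 6.97 and 5.87. The other 2 probe sets were also lowest in CPEB4 KO in every fraction. In INPUT, where no difference passed the adjusted test, that of CPEB4 KO from WT was -1.12 (SE 0.19, adjusted p = 0.253), that of CPEB4 GT/+ from WT was -0.73 and that of CPEB4 KO from CPEB4 GT/+ was -0.39. In the mean of an animal's 3 fractions Cpeb4 passed in CPEB4 KO against WT (-1.39, adjusted p = 0.00451). In INPUT the 2 animals of each genotype did not overlap with those of another. At the 3 probe sets the CPEB4 KO INPUT means were 6.77 and 6.73, above the filter at 5.52, and 5.02, below it and below the highest nonspecific control mean of 5.61. Whether the probe sets lie in the altered part of the gene was not tested.

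**Figure D1:**
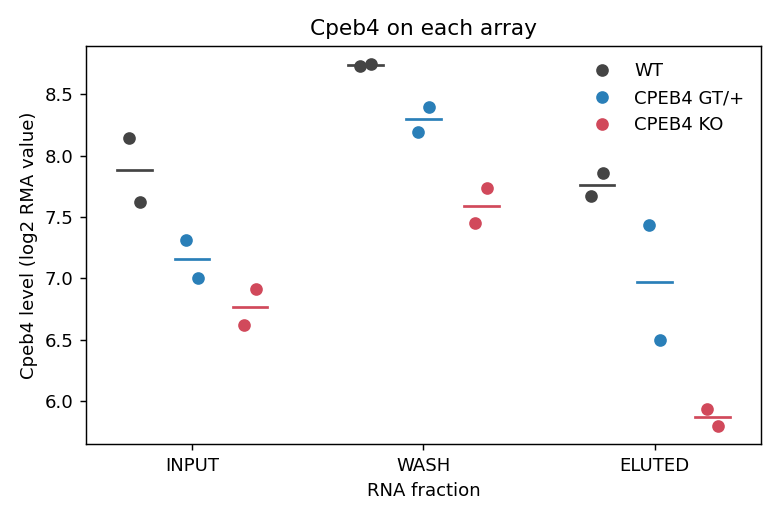
Cpeb4 level (log2 RMA value) at the probe set with the highest mean, for each of the 18 arrays by RNA fraction; points are animals, coloured by genotype, and lines are means of 2 animals. In each fraction the WT mean is the highest (7.89 in INPUT) and the CPEB4 KO mean the lowest (6.77 in INPUT).

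The first comparison asked which mRNAs were found with long rather than short tails, taking ELUTED over WASH within each of the 6 animals over the 3 genotypes. Genes of the energy and protein synthesis machinery lay on the short-tail side, in lists not matched on level. Of 71 nuclear-encoded oxidative phosphorylation subunits 70 were lower in ELUTED and 0 higher, with a median log2 ratio of -1.12. Of 70 cytosolic ribosomal protein genes 68 were lower and 0 higher, with a median of -0.96. Postsynaptic genes lay on the long-tail side of the other genes, with a median of 0.12 that is 0.30 above that of all genes and turns to -0.37 with arrays aligned on the hybridisation controls. Of 37, 17 were higher and 8 lower. Unfolded protein response genes (2 higher and 27 lower of 34, median -0.55), poly(A) tail machinery (3 higher and 34 lower of 44, median -0.48) and endothelial and mural genes (1 higher and 18 lower of 24, median -0.47) lay towards short tails. With arrays centred on their medians these 3 lists had 6 higher and 17 lower (median -0.20), 10 higher and 19 lower (-0.13) and 5 higher and 12 lower (-0.12).

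The list medians of oxidative phosphorylation and ribosomal protein genes were below 0 in 6 of 6 animals, with means over animals of -1.09 ± 0.49 (SD, n = 6) and -0.98 ± 0.45. Only 1 of 6 animals had a postsynaptic median below 0. Adjusted over the list alone the counts were the same for 5 of these lists, and 19 in place of 18 endothelial and mural genes were lower. The adjusted p at the preset correlation was 1.38e-09 for oxidative phosphorylation, 3.43e-09 for ribosomal proteins, 0.00249 for postsynaptic genes, 0.00898 for the unfolded protein response and 0.0171 for both poly(A) machinery and endothelial genes. For each of the 6 lists the adjusted p = 0.780 with an estimated correlation. With fry the adjusted p ran from 0.00534 for postsynaptic to 0.0161 for oxidative phosphorylation genes. Fry asks about a shift from 0, not from the other genes, and lists without a call, such as microglia (0.0149), passed it too. The lists of poly(A) machinery, endothelial and unfolded protein response genes lost their call when the lowest 50% of genes were left out (adjusted p = 0.388, 0.167 and 0.0971). The postsynaptic and endothelial lists lost it with INPUT as the denominator (adjusted p = 0.423 and 0.877).

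Among oxidative phosphorylation genes, Uqcrb of complex III stood at -2.24 (SE 0.27) and Ndufc2 of complex I at -2.06 (SE 0.19). The abundant Cox6a1 stood at -0.78 (SE 0.12) and Cox5b at -0.41 (SE 0.09), the latter not past the test with arrays centred on their medians. Among ribosomal protein genes, Rpl22l1 stood at -2.35 (SE 0.19), Rpl12 at -1.81 (SE 0.20) and Rps29 at -0.82 (SE 0.14). Rps2 at -0.26 turned to 0.10 with centred arrays. Among postsynaptic genes the adhesion protein Nlgn1 was 1.39 higher in ELUTED (SE 0.08), which turned to -0.31 over INPUT, and the NMDA receptor subunit Grin2b was 1.03 higher (SE 0.08). The kinase Camk2a was 0.38 higher (SE 0.07), which turned to -0.11 with arrays aligned on the hybridisation controls, and the phosphatase subunit Ppp3ca was at -0.18, which turned to 0.17 with centred arrays. Of the unfolded protein response, Derl2 stood at -1.55 and Sec61b at -1.45. Canx stood at -0.37, not past the test with centred arrays, and Hsp90b1 at -0.24, which turned to 0.12 with centred arrays. Of the poly(A) machinery, the poly(A) polymerase Papolg stood at -1.46, Cpeb4 at -1.34 (SE 0.14) and Paip2 at -0.57. Pabpn1 was at 0.02 and not called. Of the endothelial list, Ly6c1 stood at -1.35, Slc16a1 at -1.27 and Bsg at -0.88. The glucose transporter Slc2a1 was at 0.03 and not called.

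The genes with the largest ratios towards long tails were 6330415B21Rik (1.94, SE 0.07), 4931430N09Rik (1.85), Lrtm1 (1.78), the chromatin reader Zmynd8 (1.71), the striatal signalling regulator Rgs9 (1.64) and St6galnac3 (1.59). They were followed by the nuclear noncoding RNA Kcnq1ot1 (1.55), 5530401A14Rik (1.53), the cap-binding protein Ncbp3 (1.53) and Herc4 (1.52). Those towards short tails were Rnpc3, a protein of the minor spliceosome (-2.65, SE 0.13), Rpl22l1, Ssbp1, the mitochondrial DNA-binding protein (-2.34), Uqcrb and the stress neuropeptide Crh (-2.18). They were followed by Nhp2 (-2.17), Wsb1 (-2.14), Tmem60 (-2.12), C1d (-2.11) and the tubulin cofactor Tbca (-2.10). By the naming rule all of these had 6 of 6 animals on 1 side. The largest adjusted p among them was 0.000194, for Uqcrb. Not all probe sets of a gene went the same way: another probe set stood at -0.21 for Zmynd8, -0.08 for St6galnac3, -0.34 for Ncbp3, -1.29 for Herc4, 0.05 for Ssbp1 and 0.30 for C1d. The same held for Cox5b (0.53) and Slc16a1 (0.02), and for Pabpn1 (-0.58) and Slc2a1 (-0.28). Over INPUT in place of WASH, 4931430N09Rik turned to -0.08, and Lrtm1, Kcnq1ot1 and 5530401A14Rik lost their calls.

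In total 9413 of 12822 genes were called, 3196 higher and 6217 lower in ELUTED, and 3799 of these differed by at least log2 0.58. The share of called genes that were higher, 34.0%, depends on the zero. It was 65.0% with arrays centred on their medians and 2.14% with arrays aligned on the hybridisation controls, which set the median of all genes at 0.17 and -0.67 in place of -0.18. With centred arrays 28 postsynaptic genes were higher and 0 lower, and with aligned arrays 4 were higher and 19 lower. Oxidative phosphorylation genes had 62 and 71 lower, and ribosomal protein genes 59 and 69, under the same settings. With INPUT as the denominator 5654 genes were called. The Actb 3' minus 5' control difference was lower on ELUTED (-0.47 to -0.31) than on WASH arrays (-0.21 to -0.059) in 6 of 6 animals. That of Gapdh overlapped, at -0.053 to 0.062 on ELUTED and -0.13 to 0.020 on WASH arrays. It was lower on ELUTED in some animals and higher in others. Whether RNA integrity enters the ratios was not tested. The values of ELUTED arrays were also less spread (SD 1.78 to 1.90 across probe sets) than those of WASH arrays (1.96 to 2.01). The median ratio of all genes fell with level, from -0.02 without the filter to -0.33 with the lowest 50% left out. How much of the lists' ratios goes with level was not tested.

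**Figure D2:**
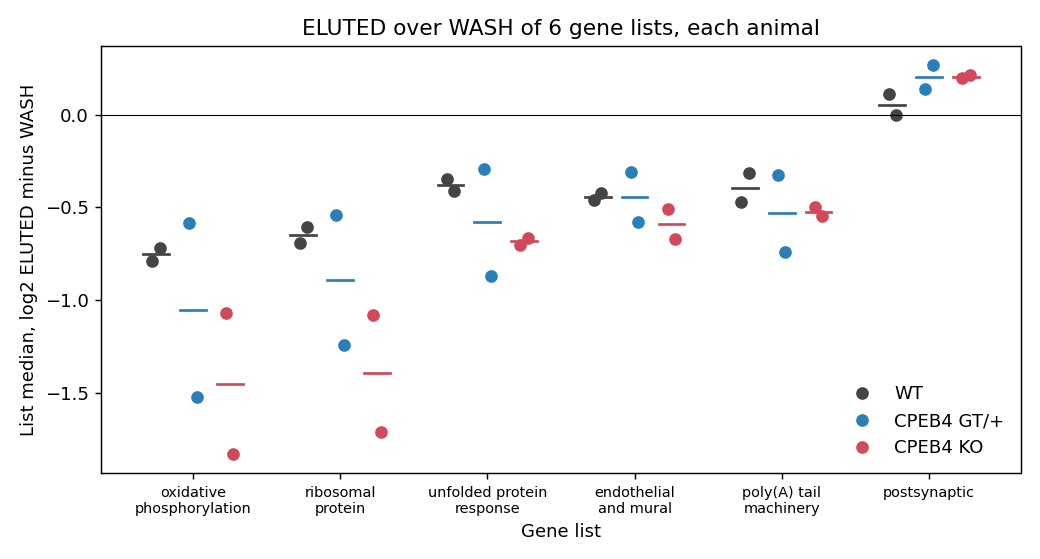
Median log2 ELUTED minus WASH of the members of 6 gene lists in each animal; points are the 6 animals, coloured by genotype, lines are means of 2 animals, and the thin line marks 0. Oxidative phosphorylation and ribosomal protein genes lie below 0 in 6 of 6 animals, with CPEB4 KO means of -1.45 and -1.40 against WT means of -0.75 and -0.65, and the CPEB4 GT/+ animals lie far apart.

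In WT alone the same question gave 607 genes higher and 2843 lower in ELUTED, and 3446 of these 3450 were called in the same direction over the 3 genotypes. Of ribosomal protein genes 29 of 70 were lower (53 adjusted over the list alone) with a median of -0.65. Of oxidative phosphorylation genes 34 of 71 were lower (55 adjusted over the list alone) with a median of -0.69. Of 37 postsynaptic genes 9 were higher and 1 lower, on both counts, with a median of 0.02 that turns to -0.43 with arrays aligned on the hybridisation controls. Poly(A) machinery (17 lower of 44, 20 adjusted over the list alone), unfolded protein response (12 of 34, and 14) and endothelial genes (11 of 24 on both counts) lay towards short tails, at medians of -0.40, -0.40 and -0.45. With centred arrays the counts were 11 lower for ribosomal protein genes, 16 lower for oxidative phosphorylation genes, 3 higher and 6 lower for poly(A) machinery (median -0.12), 2 higher and 5 lower for the unfolded protein response (-0.12) and 1 higher and 5 lower for endothelial genes (-0.17). With aligned arrays 54, 51, 23, 16 and 16 were lower. Of postsynaptic genes 16 were higher and 0 lower with centred arrays, and 1 higher and 4 lower with aligned arrays. Rnpc3 (-2.44, SE 0.23), Crh (-1.83), the endoplasmic reticulum peroxiredoxin Prdx4 (-1.82), Rpl22l1 (-1.81), Tmem60 (-1.77), Ssbp1 (-1.75), Iftap (-1.67), Wsb1 (-1.65), Serf1 (-1.64) and Trim23 (-1.63) were lowest in ELUTED. 6330415B21Rik (1.72, SE 0.13), 4931430N09Rik (1.63), Lrtm1 (1.504), Ccdc30 (1.47), Zmynd8 (1.45), 2610005M20Rik (1.41), St6galnac3 (1.39), Kcnq1ot1 (1.38), 9530059O14Rik (1.34) and Ncbp3 (1.32) were highest. Another probe set went the other way for Prdx4 (0.20), Ssbp1 (0.08), Iftap (0.33), Serf1 (0.32), Zmynd8 (-0.20) and Ncbp3 (-0.35). Cpeb4 stood at -0.97 (SE 0.25, adjusted p = 0.0277).

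The WT list tests gave adjusted p = 1.37e-07 for oxidative phosphorylation, 2.62e-07 for ribosomal proteins, 0.00337 for postsynaptic genes and 0.0254 for the other 3 lists. For all 6 the adjusted p = 0.787 with an estimated correlation. The WT count rests on few animals. It was 0 without WT replicate 1 and 0 without WT replicate 2 (limma; 2003 and 2917 genes at an unadjusted p under 0.05), when the lone WT animal is assumed to vary like the other groups. It was 6455 without either CPEB4 GT/+ animal and 1816 without either CPEB4 KO animal, which share the estimate of the spread. The endothelial and unfolded protein response lists lost their calls without WT replicate 2. With the lowest 50% of genes left out the endothelial (0.175), unfolded protein response (0.175) and poly(A) machinery lists (0.422) lost them. With INPUT as the denominator the poly(A) machinery (0.0873), unfolded protein response (0.160) and postsynaptic lists (0.948) did, and the endothelial list turned to 0.024 above all genes (0.709). With aligned arrays the unfolded protein response list lost its call (0.0877). With INPUT as the denominator 21 genes were called and 4931430N09Rik, Lrtm1, Kcnq1ot1 and 9530059O14Rik turned to -0.41, -0.05, -0.04 and -0.40. With centred or aligned arrays 68.1% or 0.661% of called genes were higher in place of 17.6%.

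The INPUT comparison of CPEB4 KO with WT asked which transcripts differ in total RNA when Cpeb4 is lost. The unfolded protein response list lay higher in CPEB4 KO, with 30 of 34 members above 0 and a median log2 difference of 0.18, led by the transporter of misfolded proteins Derl2 (0.86, SE 0.25) and the transcription factor Xbp1 (0.63, SE 0.09). Endothelial and mural genes (median 0.18, 21 of 24 above 0; Vtn 0.77 and Ly6c1 0.60), oligodendrocyte precursor genes (0.18, 14 of 15; Vcan 0.36 and Lhfpl3 0.32) lay higher too. So did replication-dependent histones (0.18, 9 of 11; H1f2 0.56 and H3c14 0.36), microglia genes (0.12, 19 of 23; C1qa 0.39 and Tmem119 0.39) and astrocyte genes (0.11, 22 of 28; Aldh1l1 0.59 and Apoe 0.59). The median of all genes was 0.03, and 0.16 with arrays aligned on the hybridisation controls. The single genes with the smallest p were lower in CPEB4 KO: Apold1, an endothelial gene at -1.40 (SE 0.13, adjusted p = 0.0523), the pseudogene Pisd-ps3 (-1.22, SE 0.12), the zinc transporter Slc39a2 (-1.10, SE 0.12) and Adam1a (-0.98, SE 0.11). Among higher genes Nnt, the mitochondrial transhydrogenase, came first at 1.25 (SE 0.15, adjusted p = 0.0979). Cox18 (0.72), Crh (0.90) and Cdhr1 (1.05) were the other higher genes of the naming rule. None of these single genes passed the adjusted test. In the mean of WASH and ELUTED, Crh (-0.05), Xbp1 (-0.07) and Adam1a (-0.19) were not past the test, and for Aldh1l1 and Vcan another probe set lay below 0.

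Of 12822 genes limma called 0, while 1404 had an unadjusted p under 0.05 (934 higher and 470 lower; 641 by chance). Adjusted over the list alone, 1 unfolded protein response gene, 2 endothelial genes, 1 astrocyte gene and 1 histone gene were higher, against 0 over all genes. The adjusted p of the lists was 2.28e-04 for the unfolded protein response, 0.00107 for endothelial, 0.00662 for precursor, 0.0255 for astrocyte, 0.0323 for microglia and 0.0437 for histone genes. With an estimated correlation the adjusted p = 0.323 for the unfolded protein response, 0.531 for endothelial, precursor and astrocyte genes, 0.950 for microglia and 0.828 for histones. Without CPEB4 KO replicate 1 all 6 list calls ended (adjusted p from 0.0692 to 0.427). Without CPEB4 KO replicate 2 that of the precursor list ended (0.0924), and without WT replicate 1 those of astrocyte, endothelial, microglia and histone genes (0.0748 to 0.463). Of the processing settings, the lowest 50% left out ended the astrocyte and histone calls, the mean of probe sets those of microglia and histone genes, quantile normalization all 3 of these, aligned arrays that of microglia and the mean of 3 fractions that of histone genes, while the microglia test turned (adjusted p from 0.0589 to 0.637 for the calls ended). Without CPEB4 KO replicate 2 limma called 260 genes higher and 9 lower, when the lone CPEB4 KO animal is assumed to vary like the other groups.

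**Figure D3:**
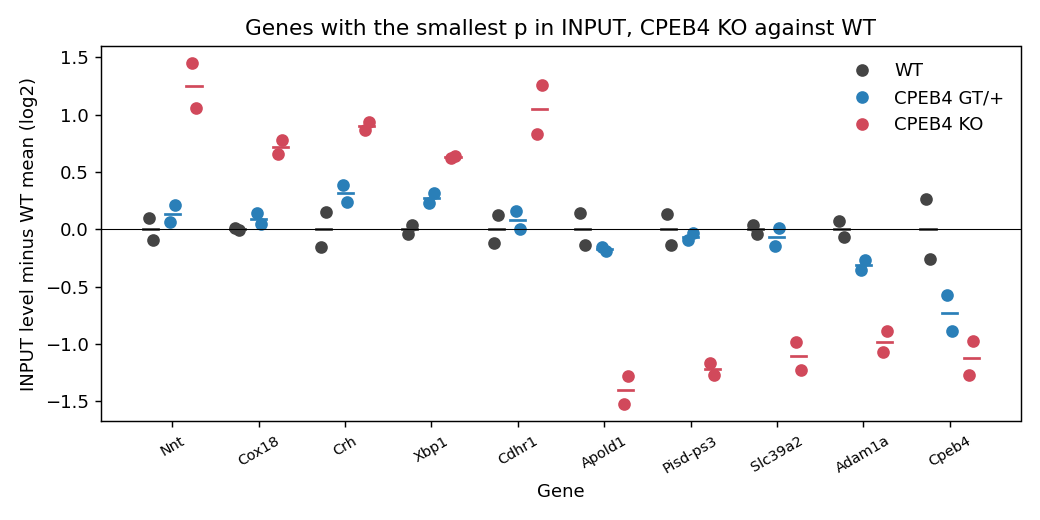
INPUT level minus the WT mean (log2) of the genes with the smallest p in CPEB4 KO against WT, higher ones first; points are the 6 animals, coloured by genotype, and lines are means of 2 animals. By the naming rule the CPEB4 KO animals lie apart from WT for each gene, from Nnt (mean difference 1.25) to Apold1 (-1.40). The CPEB4 GT/+ animals lie near WT for Pisd-ps3 and Slc39a2.

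In INPUT of CPEB4 GT/+ against WT, oligodendrocyte genes lay lower in the heterozygotes, with 0 of 27 above 0 and a median of -0.18 (Fa2h -0.50, SE 0.09; the myelin protein Mog -0.34, SE 0.09). Ependymal, choroid plexus and meningeal genes (median -0.13, 1 of 20 above 0; Ttr -0.42 and Clic6 -0.41) and genes of other brain regions (-0.18, 5 of 18; the hypothalamic peptide Pmch -1.92 and Th -0.40) lay lower too. Cortical excitatory genes (0.08, 26 of 28 above 0; Tbr1 0.35 and Rorb 0.25) and striatal projection genes (0.08, 22 of 23; the dopamine receptor Drd2 0.41 and Ido1 0.34) lay slightly higher. So did autism risk (0.07, 44 of 59; Ilf2 0.37 and Tbr1) and poly(A) machinery genes (0.08, 32 of 44; Cpeb2 0.29 and Tob1 0.28). Of single genes, Esr1, the estrogen receptor, was at -0.71 (SE 0.11), growth hormone Gh at -1.09 (SE 0.26), Baiap3 at -0.60 and Agt at -0.60. Tshz1 was at 0.68 and Sema3c at 0.61, with an adjusted p of 1.00 for each. Another probe set had the other sign for Tshz1, Sema3c, Ilf2 and Clic6.

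Limma called 0 genes, with 438 at an unadjusted p under 0.05, fewer than the 641 by chance. Adjusted over the list alone, 1 oligodendrocyte gene was lower. The adjusted p was 4.22e-13 for oligodendrocyte, 0.00184 for cortical excitatory, 0.00336 for ependymal, 0.0140 for striatal and for autism risk, 0.0147 for other regions and 0.0352 for poly(A) machinery genes. With an estimated correlation the adjusted p = 0.6002 for oligodendrocyte genes and 0.743 for the other 6 lists. Leaving out 1 animal ended calls of every list but the oligodendrocyte one. Without WT replicate 1 these were the calls of cortical excitatory, ependymal, striatal, other region and poly(A) machinery genes (adjusted p from 0.128 to 0.434), and without WT replicate 2 those of autism risk and poly(A) machinery genes (0.162 for both). Without CPEB4 GT/+ replicate 1 the call of other regions ended (0.328) and the tests of ependymal and striatal genes turned. Without CPEB4 GT/+ replicate 2 the calls of autism risk (0.0520) and poly(A) machinery genes (0.167) ended. The lowest 50% left out ended the calls of autism risk, other region, striatal and poly(A) machinery genes (0.208 to 0.447). The mean of probe sets ended those of other region and poly(A) machinery genes, and quantile normalization those of autism risk and poly(A) machinery genes. Aligned arrays (0.0978) and the mean of 3 fractions (0.218) ended that of poly(A) machinery genes. Ttr turned to 1.40 without CPEB4 GT/+ replicate 1 and to 0.73 without WT replicate 1, without which Pmch and Th also turned, to 0.12 and 0.06. WT replicate 1 also had the highest INPUT level of the pituitary hormone gene Gh (7.59, others 5.83 to 6.86). The same held for Prl (5.63, others 4.48 to 4.93), which the filter left out. Whether the dissected tissue differed between the animals, and enters these list differences, was not tested.

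In INPUT of CPEB4 KO against CPEB4 GT/+, glial and vascular genes lay higher in CPEB4 KO. These were oligodendrocyte genes in 27 of 27 cases with a median of 0.24 (Trf 0.98, SE 0.32; Qdpr 0.54, SE 0.11) and precursor genes in 13 of 15 (0.24; the glial transcription factor Sox10 0.50 and Itpr2 0.41). Astrocyte genes lay higher in 24 of 28 (0.18; Aldh1l1 0.80 and Cbs 0.49) and endothelial and mural genes in 20 of 24 (0.15; Vtn 1.06 and Acta2 0.79). Ependymal genes lay higher in 17 of 20 (0.15; Ttr 1.95 and Slc6a13 0.79) and microglia genes in 18 of 23 (0.11; C1qa 0.39 and C1qb 0.35). The unfolded protein response list lay higher with 28 of 34 members (0.16; Derl2 0.64 and Sec61a1 0.58). The median of all genes was 0.02, and 0.18 with arrays aligned on the hybridisation controls. Of single genes, Nnt (1.12), Prelp (0.82), Pnp (0.84), Gstm7 (0.84) and Esr1 (0.83) were higher. Apold1 (-1.23), Pisd-ps3 (-1.15), Slc39a2 (-1.03), Adam1a (-0.67) and 4930447C04Rik (-0.82) were lower, and none of the 10 was past the adjusted test (smallest adjusted p = 0.113). Another probe set had the other sign for Gstm7 and Itpr2.

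Limma called 0 genes here, with 1043 at an unadjusted p under 0.05 (765 higher and 278 lower). Adjusted over the list alone, 6 endothelial, 4 oligodendrocyte and 1 precursor gene were higher. The adjusted p was 1.32e-10 for oligodendrocyte, 3.25e-05 for precursor, 4.28e-05 for astrocyte, 1.32e-04 for unfolded protein response, 1.60e-04 for endothelial, 0.00276 for ependymal and 0.0109 for microglia genes. With an estimated correlation the adjusted p = 0.191 for the first 5 of these, 0.739 for ependymal and 0.766 for microglia genes. The ependymal list lost its call without CPEB4 GT/+ replicate 1 (0.694) and the microglia list without that animal (0.0599) or CPEB4 KO replicate 1 (0.348). The unfolded protein response list lost it without CPEB4 KO replicate 1 (0.0501), and the precursor list without replicate 2 of both genotypes (0.0679). With the mean of 3 fractions the microglia list turned to -0.015 relative to all genes (0.842) and C1qb to -0.028. Without CPEB4 KO replicate 2 limma called 259 genes higher and 13 lower, when the lone CPEB4 KO animal is assumed to vary like the other groups. Cbs turned to -0.19 without CPEB4 KO replicate 1.

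The ELUTED over WASH ratio of CPEB4 KO against WT asked whether loss of CPEB4 shifts mRNAs between short and long tails. Ribosomal protein genes had lower ratios in CPEB4 KO (median difference -0.66, 4 of 70 above 0; Rpl12 -1.27, SE 0.50; Rpl39 -1.25, SE 0.43), as did oxidative phosphorylation genes (-0.70, 4 of 71; Ndufc2 -1.71, SE 0.46; Uqcrb -1.64, SE 0.67). Microglia (-0.25, 4 of 23; C1qb -1.22 and Tyrobp -1.15) and unfolded protein response genes (-0.24, 5 of 34; Asns -0.85 and Derl2 -0.85) lay the same way. So did glycolysis (-0.22, 0 of 17; Tpi1 -0.65 and Ldhb -0.37) and endothelial genes (-0.16, 3 of 24; Ly6c1 -0.77 and Esam -0.56). Postsynaptic genes lay the other way relative to all genes (0.10, 25 of 37; Shank1 0.57 and Iqsec2 0.42), whose median of -0.04 moved to -0.21 with arrays aligned on the hybridisation controls. Of these 7 lists, 5 also stood apart from the other genes in ELUTED over WASH itself. Ratios were wider in the CPEB4 KO animals than in WT. The slope of an animal's ratios on the mean ratio over the 6 animals was 1.05 and 1.34 in CPEB4 KO, 0.84 and 0.71 in WT, and 0.69 and 1.38 in CPEB4 GT/+. Single genes with the smallest p were Fars2 (-1.48), Mgst3 (-0.91), Hsd11b1 (-0.80), Apex1 (-0.95) and Cryz (-1.01) on the lower side. On the higher side were 4930515G01Rik (0.79), Dnm2 (0.73), Lsm11 (0.80), Fnbp1 (0.78) and Itga5 (0.79), and each of the 10 had an adjusted p of 0.756. Cpeb4 was at -0.75 (SE 0.35), with 1 of its 3 probe sets below 0. Another probe set had the other sign for Dnm2, Rpl39 and Iqsec2.

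Limma called 0 genes, with 791 at an unadjusted p under 0.05 (170 higher and 621 lower). Adjusted over the list alone 0 members of any of the 7 lists were called. The adjusted p of the lists was 3.03e-19 for ribosomal proteins, 6.31e-19 for oxidative phosphorylation, 0.00663 for unfolded protein response, 0.00713 for postsynaptic, 0.00903 for glycolysis, 0.0130 for microglia and 0.0359 for endothelial genes. For all 7 the adjusted p = 0.694 with an estimated correlation. Without WT replicate 1 the calls of endothelial, glycolysis and unfolded protein response genes ended (adjusted p from 0.0760 to 0.139). Without CPEB4 KO replicate 1 that of endothelial genes ended (0.0700), and without CPEB4 KO replicate 2 those of endothelial (0.116), microglia (0.175) and postsynaptic genes (0.117). The 18S ribosomal RNA control was higher on the CPEB4 KO ELUTED arrays (13.23 and 13.14) than on the other 4 ELUTED arrays (12.50 to 12.60), and 12.88 on the WASH array of CPEB4 KO replicate 1 against 12.17 to 12.46 on the other WASH arrays. With each animal's ratios scaled to a common spread the endothelial (0.959), microglia (0.152), postsynaptic (0.959) and unfolded protein response lists (0.380) lost their calls. The endothelial call also ended with the lowest 50% left out (0.156), quantile normalization (0.0721), centred arrays (0.0516) or a replicate block (0.0505), and the glycolysis call over INPUT (0.0998).

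In the ratio of CPEB4 GT/+ against WT, oxidative phosphorylation (median -0.28, 1 of 71 above 0; Ndufc2 -0.89 and Uqcrb -0.70) and ribosomal protein genes (-0.25, 3 of 70; Rpl12 -0.69 and Rpl36a -0.61) lay lower. Postsynaptic genes lay higher (0.07, 29 of 37; Nlgn1 0.38 and Iqsec2 0.38). The lower medians rest on replicate 2, without which they lay above that of all genes, by 0.10 for oxidative phosphorylation and 0.042 for ribosomal protein genes. Plcg1 (0.74), Zfp280d (0.68), Fxyd4 (0.60), Irx6 (0.62) and Nudt5 (0.58) had higher ratios. Timm9 (-0.75), Zfhx4 (-0.84), Rsrc1 (-0.60), Hgh1 (-0.59) and Ugp2 (-0.68) had lower ones, and each of the 10 had an adjusted p of 1.00. Cpeb4 was at -0.35 (SE 0.35), and at 0.22 without CPEB4 GT/+ replicate 2. Another probe set had the other sign for Cpeb4, Zfp280d, Nudt5, Zfhx4 and Iqsec2. Limma called 0 genes, with 115 at an unadjusted p under 0.05, and 0 list members adjusted over the list alone. The adjusted p was 2.95e-07 for oxidative phosphorylation, 3.81e-07 for ribosomal proteins and 0.00338 for postsynaptic genes. The adjusted p = 0.841 with an estimated correlation for all 3. The postsynaptic call ended without CPEB4 GT/+ replicate 2 (0.329) and without WT replicate 2 (0.0517). With animals scaled to a common spread all 3 calls ended (adjusted p = 0.455, 0.431 and 0.455).

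In the ratio of CPEB4 KO against CPEB4 GT/+, ribosomal protein genes (median -0.37, 6 of 70 above 0; Rpl39 -1.08 and Rps21 -0.92) and oxidative phosphorylation genes (-0.38, 7 of 71; Ndufb5 -1.10 and Uqcrq -1.003) had lower ratios in CPEB4 KO. So did glycolysis genes (-0.16, 1 of 17; Tpi1 -0.53 and Slc2a1 -0.27) and endothelial genes (-0.16, 6 of 24; Acta2 -0.46 and Pecam1 -0.44), while the median of all genes was -0.03, and -0.25 with arrays aligned on the hybridisation controls. Lsm11 (0.79), 4930515G01Rik (0.76), C1ql3 (0.70), the imprinted gene Ndn (1.29) and Myo19 (0.68) had higher ratios. Matn2 (-0.75), Scara3 (-0.78), Cryz (-0.85), Lamtor1 (-0.66) and H2-Ab1 (-0.76) had lower ones, and each of the 10 had an adjusted p of 1.00. Cpeb4 was at -0.40 (SE 0.35), and at 0.17 without CPEB4 GT/+ replicate 1. Another probe set had the other sign for Cpeb4, H2-Ab1 and Uqcrq. Limma called 0 genes, with 237 at an unadjusted p under 0.05, and 0 list members adjusted over the list alone. The adjusted p was 1.21e-12 for ribosomal proteins, 1.56e-11 for oxidative phosphorylation, 0.0149 for glycolysis and 0.0419 for endothelial genes. The adjusted p = 0.833 with an estimated correlation for all 4. Without CPEB4 GT/+ replicate 1 the calls of ribosomal protein (0.421), glycolysis (0.650) and endothelial genes (0.596) ended and the test of oxidative phosphorylation genes turned. Without CPEB4 KO replicate 2 all 4 ended (0.109 to 0.218). The endothelial call also ended without WT replicate 1 or 2 (0.0539 for both), CPEB4 GT/+ replicate 2 (0.0623) or CPEB4 KO replicate 1 (0.0588). The glycolysis call ended without CPEB4 KO replicate 1 (0.0588), over INPUT (0.225) and with aligned arrays (0.0638), and the endothelial call with the lowest 50% left out (0.0853), scaled animals (0.370) or aligned arrays (0.0852).

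Across the 12822 genes, which are not independent replicates, the effects of CPEB4 KO and CPEB4 GT/+ against WT correlated at r = 0.371 in INPUT and at r = 0.692 in the ratio. Both effects share the WT animals, which alone gives a correlation. Unchanged groups were simulated with each animal as a random mix of the differences between animals within the genotypes. They gave a median r of 0.638 (-0.844 to 0.990 in 95% of 1000 draws) in INPUT. In the ratio the median was 0.646 (-0.863 to 0.993). Such wide ranges hold most possible values of r, so the simulation cannot decide whether either value stood apart. The ratio value of 0.692 rests on CPEB4 GT/+ replicate 2, without which r was -0.0196. For the INPUT effects r was 0.164 without CPEB4 KO replicate 2 and 0.561 without WT replicate 1.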

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

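The tests chosen only after the result was seen were those of the hybridisation controls, of the ribosomal RNA control, of genotype as the whole cause, of 1 scale factor per animal, of the INPUT arrays, of the cell mix and of glial and vascular RNA.

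Several gene lists passed a test of the difference between genotypes in the ELUTED over WASH ratio at camera's preset correlation of 0.01. None passed with an estimated correlation, which was 0.78 for ribosomal protein and 0.93 for oxidative phosphorylation genes. By animal, the CPEB4 GT/+ medians of ribosomal protein genes (-0.54 and -1.24) overlapped those of WT (-0.69 and -0.61) and CPEB4 KO (-1.08 and -1.71). Those of oxidative phosphorylation genes (-0.58 and -1.52) overlapped WT (-0.79 and -0.72) and CPEB4 KO (-1.07 and -1.83) too. For CPEB4 KO against WT the list medians differed by -0.66 for ribosomal protein genes, -0.70 for oxidative phosphorylation, -0.25 for microglia, -0.24 for the unfolded protein response, -0.22 for glycolysis, -0.16 for endothelial and mural and 0.10 for postsynaptic genes. For CPEB4 GT/+ against WT they differed by -0.25 for ribosomal protein, -0.28 for oxidative phosphorylation and 0.069 for postsynaptic genes. For CPEB4 KO against CPEB4 GT/+ they differed by -0.37 for ribosomal protein, -0.38 for oxidative phosphorylation, -0.16 for glycolysis and -0.16 for endothelial and mural genes.

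These differences go with ratios that were wider on average over genes, though not in every list, in the CPEB4 KO animals and CPEB4 GT/+ replicate 2. Genotype as the whole cause of the spread over the 6 animals is argued against by the 2 CPEB4 GT/+ animals, whose slopes lay 0.685 apart, more than the 0.416 between the CPEB4 KO and WT means, while genotype as a part of it stays open. An array effect, with less labelled RNA on ELUTED than on WASH arrays, may contribute: an animal's slope went with the ELUTED minus WASH level of the hybridisation controls (Pearson r = 0.846, exact permutation p = 0.0222; Spearman rho = 0.886, exact permutation p = 0.0333; 6 animals, 720 permutations, 1 relation), and r was 0.882 without CPEB4 GT/+ replicate 1 and CPEB4 KO replicate 2. After scaling each animal to a common spread the CPEB4 KO minus WT difference was -0.32 (SE 0.12, 95% interval -0.85 to 0.22) for ribosomal protein genes and -0.22 (SE 0.18, -0.98 to 0.54) for oxidative phosphorylation genes. With 2 animals against 2, a scale factor per animal as the whole cause cannot be told apart from a further effect of genotype on these 2 lists, nor can ribosomal RNA on the ELUTED arrays, whose 18S control lay at least 0.54 higher in CPEB4 KO than on the other ELUTED arrays, CPEB4 GT/+ replicate 2 included.

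The genes with the largest INPUT differences in CPEB4 KO, such as Nnt, Apold1, Pisd-ps3 and Slc39a2, could reflect the mice's background, and Nnt is known to carry a deletion in the C57BL/6J strain. Genes carried along with the targeted locus are argued against, with 0 of the 20 genes of smallest p among the 100 tested genes nearest Cpeb4. The largest cell type median was 0.18, while Nnt differed by 1.25 and Apold1 by -1.4 in INPUT. A change in the mix of the listed cell types as a whole, large enough for such differences, is argued against. A smaller change in that mix is not. Medians of broad lists cannot speak to genes of a small cell group or a neighbouring region, so a different mix there stays open. Segments of another strain elsewhere stay open: 7 of the 50 genes of smallest p had another within 10 tested genes, against a median of 4 in random draws, 0.113 of which had as many. A fault of the INPUT arrays alone is argued against for 7 of the 10 named genes, which differed the same way in the mean of WASH and ELUTED, adjusted over the 10 (Apold1 -1.72, Cpeb4 -1.52, Cdhr1 1.36, Pisd-ps3 -1.32, Nnt 0.67, Slc39a2 -0.44 and Cox18 0.28), and stays open for Crh, Xbp1 and Adam1a, whose median share of -5.97% there decides nothing, since they were set apart by not passing in those fractions. An effect of the loss of CPEB4 stays among the open explanations.

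The higher INPUT levels of unfolded protein response genes in CPEB4 KO, at a median of 0.18, could come from INPUT arrays that lean towards WASH arrays, since INPUT differences went with the mean ratio at r = -0.379 across genes, which are not independent replicates. Of random lists matched for the ratio and the mean level, 99.9% had a lower median (matched median 0.08, 95% from 0.03 to 0.14). This does not decide whether such a lean is the whole cause, since the list had the smallest adjusted p of 22 on the same values. The draws also took genes, not animals, as the unit. More glial and vascular RNA cannot be told apart from an effect of genotype, since the lowest of the 5 glial and vascular medians lay 0.014 above that of all genes, against 0.15 for the unfolded protein response list, and the lists moved by unequal amounts. An effect of the loss of CPEB4 stays open too.

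The real split into ELUTED and WASH gave the most genes, which argues against chance as the source of the difference between the fractions. It does not cover each gene counted, and a share of 1 in 32 is the lowest that the splits within pairs can give. Of the 32 splits that part every animal's pair of arrays, 1, the real one, gave as many genes, 9413 against 3937 in the highest other. Of 100 drawn from the 462 splits of the 12 arrays into equal groups, fitted without the animal, 1, the real one, gave as many, 9811 against 5217.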

How the results depend on the processing

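The settings chosen only after the data were seen were the scaling of animals to a common spread, the alignment on hybridisation controls, leaving out replicate 2 of both CPEB4 GT/+ and CPEB4 KO, the crossed block and the mean of 3 fractions. For the changes below the cause was not tested, except that leaving out animals leaves fewer samples.

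Over all settings and leave-outs, values of the 190 gene results kept direction and side of the threshold 3307 times, lost the call 79 times, reversed 37 times and passed the threshold newly in the remaining cases. The 46 list calls held 684 times, were lost 192 times and reversed 10 times. Of the 684, 46 came with trend and robust settings, which do not enter the list test and could not change it. All 46 list calls were lost with an estimated correlation and 40 with fry. Of the processing settings, the lowest 50% left out ended 14, the scaling of animals 8, leaving out replicate 2 of both genotypes 8, INPUT as the denominator 7, quantile normalization 6, aligned arrays 5, the mean of probe sets 4, the mean of 3 fractions 2, and centred arrays, each replicate block and the fit of only 2 genotypes 1 each. Of the counts, 122 stayed within 1.5 times, 24 became larger and 6 smaller. A count of 0 that stayed 0, as in most settings of the comparisons between genotypes, was taken as within 1.5 times. The 122 therefore does not measure how stable the other counts were. The counts of CPEB4 GT/+ against WT in INPUT and in the ratio, and that of CPEB4 KO against CPEB4 GT/+ in the ratio, were 0 under each setting run (limma; 438, 115 and 237 genes at an unadjusted p under 0.05).

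For ELUTED over WASH over the 3 genotypes, 9413 genes became 5654 over INPUT, and from 7553 to 10255 with 1 animal left out. In WT, 3450 became 5311 with a random block, 21 over INPUT, 8023 with animals scaled and 7489 without replicate 2 of both CPEB4 GT/+ and CPEB4 KO, and from 0 to 6455 with 1 animal left out.

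For INPUT of CPEB4 KO against WT, limma's 0 genes (1404 at an unadjusted p under 0.05) became 4 with the lowest 50% of genes left out, 2 with the mean of probe sets, 1 with quantile normalization, 3 with centred arrays, 5 with trend and robust settings, 4 with a random block, 162 with aligned arrays, 223 without replicate 2 of both CPEB4 GT/+ and CPEB4 KO, 4 with the mean of 3 fractions, and from 0 to 269 with 1 animal left out. The few genes were Apold1 in 7 settings, Pisd-ps3 in 6, Nnt in 4, Adam1a in 3, Slc39a2 in 2 and Cpeb4 in 1. For CPEB4 KO against CPEB4 GT/+, 0 (1043 at an unadjusted p under 0.05) became 3, 1, 5, 2, 228, 185 and 4 with the lowest 50% left out, the mean of probe sets, trend and robust settings, a random block, aligned arrays, without replicate 2 of both and the mean of 3 fractions, and from 0 to 272 with 1 animal left out. The few were Pisd-ps3, Apold1, Nnt, Slc39a2, Esr1 and Zic2, the last chosen after its values were seen. For the ratio of CPEB4 KO against WT, 0 (791 at an unadjusted p under 0.05) became 3 with the crossed block, Cstb (-1.71), H2bc4 (-1.55) and Naa38 (-1.74), chosen after their values were seen, and was 0 with each animal left out.

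Results that reversed are given with the value under that setting, list medians relative to all genes. For ELUTED over WASH over the 3 genotypes these were 4931430N09Rik (-0.076), Nlgn1 (-0.31) and Pabpn1 (-0.17) over INPUT, and Camk2a (-0.11), Pabpn1 (-0.47) and Slc2a1 (-0.46) with aligned arrays. They were also Hsp90b1 (0.12), Ppp3ca (0.17) and Rps2 (0.098) with centred arrays, and Pabpn1 (-0.23) and Slc2a1 (-0.12) with the mean of probe sets. In WT over INPUT they were 4931430N09Rik (-0.41), 9530059O14Rik (-0.40), Kcnq1ot1 (-0.036), Lrtm1 (-0.050) and the endothelial list (0.024). In INPUT with the mean of 3 fractions they were C1qa (-0.074) and the test of the microglia list (0.0024) for CPEB4 KO against WT, and C1qb (-0.028) and the microglia list (-0.015) for CPEB4 KO against CPEB4 GT/+. In the ratio of CPEB4 GT/+ against WT they were Cpeb4 with animals scaled (0.020) and Hgh1 over INPUT (0.13), and in that of CPEB4 KO against CPEB4 GT/+ Cpeb4 with the mean of probe sets (0.020).

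With 1 animal left out, Pabpn1 in ELUTED over WASH over the 3 genotypes ran from -0.030 without CPEB4 GT/+ replicate 1 to 0.078, and was -0.016 without WT replicate 2. In INPUT of CPEB4 KO, Lhfpl3 against WT ran from -0.0017 without WT replicate 2 to 0.64, and Cbs against CPEB4 GT/+ from -0.19 without CPEB4 KO replicate 1 to 1.16. In INPUT of CPEB4 GT/+ against WT, Pmch ran from -3.95 to 0.12 and Th from -0.85 to 0.061, the highest without WT replicate 1. Ttr ran from -2.25 to 1.40, the highest without CPEB4 GT/+ replicate 1. Without that animal the tests of the ependymal (-0.26 to -0.040) and striatal lists (0.013 to 0.17) turned.

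In the ratio of CPEB4 GT/+ against WT with 1 animal left out, Cpeb4 ran from -0.93 to 0.22, Rpl12 from -1.47 to 0.084, Rpl36a from -1.32 to 0.105, Uqcrb from -1.76 to 0.35, the ribosomal protein list from -0.53 to 0.042 and the oxidative phosphorylation list from -0.62 to 0.10. The highest values came without CPEB4 GT/+ replicate 2, and were the same when CPEB4 KO replicate 2 was left out too. In the ratio of CPEB4 KO against CPEB4 GT/+, Cpeb4 ran from -0.97 to 0.17 and the oxidative phosphorylation list from -0.78 to -0.048, where its test turned, the highest without CPEB4 GT/+ replicate 1. Across genes, the correlation of the CPEB4 KO and CPEB4 GT/+ effects on the ratio, 0.692, ran from -0.0196 without CPEB4 GT/+ replicate 2 to 0.778 without WT replicate 1, and was 0.0987 without replicate 2 of both genotypes.

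The share of genes higher in ELUTED among those called depended on the filter on dim genes, at 42.0% without a filter and 21.2% with the lowest 50% left out. What signal over background limits was not tested. The planned test of 3' UTR elements was not run.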

Other observations

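The test chosen only after the data were seen was that of pituitary hormone genes.

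Of the lists without a call in ELUTED over WASH over the 3 genotypes, the median log2 ratios were -0.52 for microglia, -0.45 for replication-dependent histones, -0.37 for astrocyte, -0.29 for oligodendrocyte, -0.26 for glycolysis, -0.20 for immediate early, -0.18 for cortical excitatory, -0.10 for GABA interneuron, -0.10 for ependymal, -0.08 for striatal projection, -0.08 for oligodendrocyte precursor, -0.07 for other region, -0.06 for noncoding RNA, -0.04 for autism risk, -0.03 for presynaptic and 0.04 for blood genes, against -0.18 for all genes. The smallest adjusted p among them at the preset correlation was 0.0502, for microglia and oligodendrocyte genes. The mitochondrially encoded list had 0 kept members.

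In INPUT, Xist had means of 10.80, 10.80 and 10.74 in WT, CPEB4 GT/+ and CPEB4 KO (n = 2 each). The Y-linked genes had 4.74, 4.65 and 4.69 for Eif2s3y, 5.10, 5.01 and 4.96 for Kdm5d, and 4.40, 4.46 and 4.36 for Uty.

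Of the pituitary hormone genes, Gh had INPUT means of 7.23 ± 0.51 (SD, n = 2) in WT, 6.14 ± 0.43 in CPEB4 GT/+ and 5.88 ± 0.07 in CPEB4 KO. Prl had 5.25, 4.73 and 4.49, Pomc 6.22, 6.23 and 6.18, Tshb 6.71, 6.18 and 6.62, Cga 5.21, 5.10 and 5.11, Lhb 5.82, 5.66 and 5.74, Fshb 4.29, 4.21 and 4.31, and Gnrhr 4.41, 4.34 and 4.27.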
